A study of Saccharomyces cerevisiae and Caenorhabditis elegans with 17 samples.

How the data were processed

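Ribosome profiling libraries were made from whole N2 worms at adult days 1, 6 and 12 and from yeast of the strain labelled BY4741, wild type or lacking SCH9, at chronological days 0, 2 and 4, giving 17 libraries in 9 groups. Per the labels' protocols, worms were raised at 20 °C on agar plates and frozen in liquid nitrogen, and yeast were cultured at 30 °C in synthetic complete medium, collected by rapid filtration and frozen. The lysates were treated with RNase I, ribosomes were pelleted through sucrose, fragments of 20 to 35 nt were selected on gels, a 3′ linker was added, ribosomal RNA was depleted with Ribo-Zero, and the cDNA was circularised, per the labels' protocols. Per the submitters' processing notes, CASAVA 1.8, cutadapt 1.4.2 and Bowtie 1.0.0 were used with the builds ce11 (WBcel235) and sacCer3 (R64), with the role of each not stated. The read length filter, the handling of reads that match several places, the use of strand and the offset from read end to ribosomal site are not given in the sources used here. RNase digestion, gel selection and the ligation of linkers each favour some fragments, so occupancies at single codons carry the sequence preferences of these steps.

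The deposited tables hold whole-number footprint counts per codon, not normalised by the authors, with 7 positions before the start codon and 7 after the stop codon of each coding sequence, as seen in the files. Peaks at codon 2 and at the stop codon were read as positions of the ribosomal A site, so each count is taken as the codon in the A site. From these the following values were computed here. Counts were summed over all codons of a coding sequence to give gene counts. For worms 1 transcript per gene was kept, the one with most codons (20219 of 20222 sequences), and 20206 worm and 5772 yeast sequences had a complete reading frame. Total counts per library were 26739848 and 24502666 (worm day 1), 48854691 (day 6), 22183258 and 22802273 (day 12), 26316111 and 23879343 (wild-type yeast day 0), 12191332 and 21706486 (day 2), 17329903 and 24230063 (day 4), 36874583 and 30555437 (deletion strain day 0), 29606324 and 25850513 (day 2) and 24216027 and 47618536 (day 4). Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom between 6.7 and 256.2), so none was a duplicate. The common biological coefficient of variation was 0.069 in worms and 0.173 in yeast.

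Gene counts were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment over genes, adjusted p under 0.05) in R 4.3.3. All 5 worm libraries and all 12 yeast libraries shared an estimate of the spread within each organism, with group as the only term. The yeast contrasts were day 2 and day 4 against day 0 in each strain, deletion strain against wild type at days 0 and 4, and the difference of the day 4 changes between strains. CPM values in the text are scaled by TMM. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of the organism that had at least 5 measured members, and repeated with an estimated correlation. The 17 yeast lists were cytosolic ribosome, ribosome biogenesis, mitochondrial ribosome, heat shock and chaperones, ribosome-associated chaperones, general stress and reserve carbohydrates, gluconeogenesis with glyoxylate cycle and acetate use, glycolysis and fermentation, hexose transporters, tricarboxylic acid cycle and oxidative phosphorylation, peroxisomal beta-oxidation, amino acid biosynthesis, proteasome, tRNA synthetases, elongation and termination factors, ribosome quality control, and autophagy with vacuolar proteases. All 416 of their members matched the reference gene table of R64. The worm tables carry sequence identifiers only, and no worm gene-name reference was used here, so the worm lists chosen by gene symbol matched 0 genes. They were replaced, after the data had been seen, by worm counterparts of the yeast lists, defined as reciprocal best protein matches (BLAST+ 2.17.0, expect value 1e-10, 1762 worm genes), and by genes with at least 20 Gly-X-Y triplets. The tests, yeast lists, contrasts, alternatives and the rule for named genes were chosen before the data were examined. Mating-type, haploid-specific and strain-marker genes were chosen after the first results were seen.

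Relative occupancy was the count at a codon over the mean count per analysed codon of its gene, leaving out the first and last 20 codons, in 6593 worm and 3883 yeast genes with at least 0.5 counts per codon in every library. Log2 mean occupancies of 20 residues and 8 motifs (at least 3 lysine or arginine, at least 3 lysine, at least 3 arginine, windows of 10 with at least 6 basic residues, at least 2 and at least 3 proline, at least 4 acidic residues and at least 4 serine) were compared with limma, over each run and the 2 codons after it. The day 2 contrasts of occupancy came from the same fit but were not among the comparisons first chosen. There were 6710 basic runs in 3084 worm genes and 3567 in 1859 yeast genes. Single positions with a mean of at least 5 counts were compared with edgeR using the log of the gene's total over the analysed codons as offset. The biological coefficient of variation per position was 27.2% in worms and 31% in yeast, at a median of 10 and 11 counts per position. Median polarity per library and the shares of counts near the ends were described without a test. The intervals and the 3-count floor cover counting error or the spread between libraries only.

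Named genes were SCH9, then per list up to 3 called members with the smallest adjusted p in the main direction and 1 in the other, and the 5 largest rises and 5 largest falls with at least 50 CPM in a group and non-overlapping replicates. The text uses part of these. Named positions were the 5 strengthened and 3 weakened ones with the largest fold and at least 20 counts in each library of the stronger group, of which the text uses part. The named worm positions, where none passed, were those with the smallest p. Genes sharing at least 10% of their 28-base windows with another gene (1725 worm, 329 yeast) and 94 overlapping yeast genes were treated as uncertain.

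Alternatives were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a replicate block, only the compared groups, leaving out the first and last 20 codons, leaving out each library in turn, at least 20 counts per position, an offset without the position itself, all codons but the first and last, Fisher's exact test on pooled counts, occupancy capped at 20, the codon 1 position upstream, means per gene first, and at least 2 counts per codon. The edgeR tests of genes and positions, camera and the limma test of occupancy were also run on simulated data. These data used spreads estimated from the libraries here, so they came after the fits. Far fewer genes were changed in them than were called in the age comparisons, and all positions of an organism were given the same dispersion. The recovered shares below therefore need not hold for the real fits. DESeq2 and Fisher's exact test were not run on such data. With 200 changed genes, edgeR recovered 70% of 2-fold and 86% of 4-fold changes in the worm comparison, 81% and 96% in wild-type yeast at day 4, 82% and 94% in the deletion strain at day 4, and 30% and 83% for the difference between strains. Of simulated 8-fold changes at positions with at least 20 counts, 80.1% were recovered in worms, 69.7% in wild type, 80.5% in the deletion strain and 14.8% for the difference between strains. Under 20 counts, 45.8%, 41.6%, 50.6% and 5.4% were recovered in that order. For 4-fold changes it was 35.8%, 23.6%, 27.7% and 2.9% at 20 counts or more. Under 20 counts it was 8.7%, 5.3%, 11.1% and 0.3%. Of simulated 20% changes in occupancy, 74.2%, 70.9%, 73.2% and 47.9% were recovered in the same order. These are averages over features drawn at random from the 28, and they need not hold for basic runs. The standard error of basic runs was log2 0.133 in worms and 0.182 in wild-type yeast, against 0.055 and 0.054 for lysine codons. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and data.table (version 1.17.8) in R, were used for the rest. Sequence outside the coding sequences and correlations between comparisons that share libraries were left out.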

Results

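Ribosome footprints were sequenced from whole N2 worms (the wild-type laboratory strain of Caenorhabditis elegans) at adult day 1 (n = 2), day 6 (n = 1) and day 12 (n = 2), and from budding yeast at chronological days 0, 2 and 4. The yeast were a wild-type strain and a long-lived strain lacking SCH9, with n = 2 at each age. SCH9 encodes a nutrient-responsive protein kinase that promotes growth. Chronological age is time spent by non-dividing cells in a culture that has used up its glucose. Whether the day 0 cells were already in that state was not tested directly. In both strains every gene of the gluconeogenesis list was higher at day 2 than at day 0, as given below. Every cytosolic ribosomal protein gene was lower. These changes argue against the day 0 cells having been in the same state as the later cells. Day 4 was not compared with day 2, so an early change of state and later ageing were not told apart. A footprint is an mRNA fragment protected by a ribosome, and the values are footprint counts at each codon, so a gene's count reflects both its mRNA level and its translation. RNA abundance libraries were not analysed here. All values are relative to the library, and the total amount of translation in an animal or a cell was not measured.

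Total counts per library lay between 22183258 and 48854691 in worms and between 12191332 and 47618536 in yeast. The share of codons with at least 1 count was 28.2% to 34.4% in worms and 49.9% to 78.2% in yeast. Replicates correlated over genes with Pearson's r of log2 CPM (counts scaled to the same library total) between 0.968 in wild-type day 4 yeast and 0.996 in the deletion strain at day 0, where genes are not independent replicates. The first principal component held 73.2% of the variance in worms and 77.3% in yeast. The worm day 6 library had no replicate and entered no comparison. Nothing in the labels states that replicates came from separate cultures or populations, so the p-values measure only the spread between these libraries, which may be technical.

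The deleted gene was examined first. SCH9 (chromosome VIII, 509363 to 511837, R64 assembly, protein-coding) had 151 ± 0.161 CPM in wild-type yeast at day 0, 201 ± 5.87 at day 2 and 190 ± 3.04 at day 4 (SD, n = 2 each). In the deletion strain it had 2.07 ± 0.791, 5.94 ± 0.191 and 1.97 ± 1.08 CPM. Per library, wild-type counts lay between 2570 and 4455 and deletion-strain counts between 40 and 200. The strain difference was 71.9-fold at day 0 (log2 −6.17, SE 0.36, adjusted p = 3.91e-06) and 101-fold at day 4 (log2 −6.65, SE 0.36, adjusted p = 2.35e-05) by edgeR's quasi-likelihood test. Every library thus matched its label for SCH9. The rest of the labelled genotype is taken up next.

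Genes of mating type and ploidy also separated the strains. Both strains carry the label BY4741, a haploid MATa laboratory strain with deletions in HIS3, LEU2, MET17 and URA3. The alpha-pheromone gene MF(ALPHA)1 had 11.8 ± 2.72 CPM in wild type and 1680 ± 276 in the deletion strain at day 0. The alpha-agglutinin gene SAG1 had 4.1 ± 0.655 and 602 ± 81.7 CPM. All 5 alpha-specific genes examined were higher in the deletion strain at day 0, with a median log2 difference of 7.15. All 10 haploid-specific genes were also higher, with a median of 4.07, among them the pheromone-pathway kinase gene FUS3 (0.677 ± 0.0261 against 31.5 ± 0.195 CPM). None of 7 a-specific genes differed by edgeR, and their median was 0.476 CPM in wild type and 0.262 in the deletion strain, against a median of 41.8 over all tested genes in wild type. MET17 had 4170 ± 513 CPM in wild type and 2500 ± 124 in the deletion strain at day 0, while LEU2 had 0.0268 ± 0.0379 and 0. The MET17 counts go against the label BY4741 in both strains, as do the low counts on a-specific genes. LYS2, another marker gene, had 224 ± 15.7 and 249 ± 5.37 CPM at day 0. URA3 had no counts in either strain at day 0. HIS3 was covered except for a gap of 66 codons, from codon 102 to codon 167 of 221. At day 4 the alpha-specific genes had a median strain difference of −0.28 (2 higher, 2 lower) and the haploid-specific genes one of 1.92 (6 higher).

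**Figure D1:**
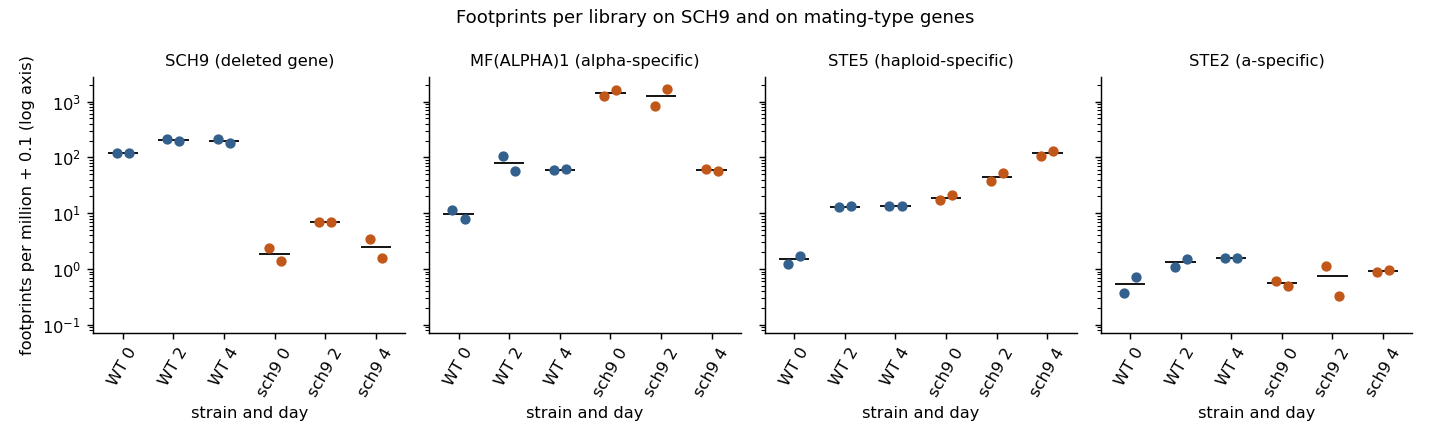
Footprint CPM plus 0.1 (log axis, without TMM scaling) on SCH9, an alpha-specific, a haploid-specific and an a-specific gene, for each yeast library by strain and day, with a bar at the mean of 2 libraries. SCH9 was low in every sch9 library, MF(ALPHA)1 was high in sch9 libraries at days 0 and 2, and STE2 was low in all.

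The worm libraries address how footprint counts per gene change with age in whole animals. Changes of mRNA level, of translation and of the share of each tissue cannot be told apart in them. At day 12, the worm counterparts of yeast cytosolic ribosomal proteins carried fewer footprints than at day 1 in all 43 measured cases, with a median log2 change of −1.07 (camera adjusted p = 6.46e-21, and adjusted p = 0.32 with an estimated correlation). The counterpart of RPS12, a small-subunit protein, fell from 1530 ± 151 to 540 ± 64.5 CPM (SD, n = 2), a 2.82-fold decrease (log2 −1.50, SE 0.11, adjusted p = 3.76e-13). The counterpart of RPL30 was 2.37-fold lower (adjusted p = 1.9e-11). Autophagy counterparts went the other way, with 6 of 7 higher and a median of 0.47 (adjusted p = 0.0355, and adjusted p = 0.32 with an estimated correlation). The counterpart of ATG8, the ubiquitin-like protein of autophagosome membranes, rose from 353 ± 8.67 to 614 ± 0.272 CPM (log2 0.80, SE 0.09, adjusted p = 9.33e-09). Counterparts were defined by reciprocal best protein match, because no table of worm gene names was used here. Worm genes without such a match are absent from these lists, here and in the paragraphs that follow. Camera compared each list with all other tested worm genes, not with the other genes that had a yeast match. A fall shared by conserved genes was therefore not told apart from falls particular to a list.

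Footprints on other parts of the translation machinery also fell. Of 9 counterparts of elongation and termination factors, 8 fell and 1 rose (median −0.99, adjusted p = 8.52e-05, and adjusted p = 0.32 with an estimated correlation). Among them the counterpart of HYP2, the elongation factor eIF5A that helps ribosomes through difficult sequences, went from 1960 ± 235 to 745 ± 92 CPM (2.64-fold, adjusted p = 4.32e-12). The member that rose was the counterpart of TEF1 and TEF2, encoding elongation factor 1A (log2 0.62, SE 0.10, adjusted p = 2.86e-06), which shares 16.6% of its sequence windows with other genes and is uncertain. All 18 tRNA synthetase counterparts fell (median −0.63, adjusted p = 1.24e-05, and adjusted p = 0.32 with an estimated correlation), for example GRS1 by 1.89-fold. Of 23 ribosome biogenesis counterparts, 19 fell and none rose (median −0.35, adjusted p = 0.00466, and adjusted p = 0.32 with an estimated correlation), with 1 higher and 19 lower adjusted over the list alone.

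Genes of protein quality control and energy metabolism moved in the same direction. All 31 proteasome counterparts fell (median −0.71, adjusted p = 1.27e-09, and adjusted p = 0.32 with an estimated correlation), including RPN8 of the regulatory particle, which went from 462 ± 22.3 to 228 ± 7.09 CPM. Of 10 heat shock and chaperone counterparts 9 fell (10 adjusted over the list alone), with a median of −0.96 (adjusted p = 2.7e-06, and adjusted p = 0.32 with an estimated correlation). The counterpart of the Hsp40 gene YDJ1 was 2.61-fold lower (log2 −1.38, SE 0.09, adjusted p = 2.98e-14). Counterparts of the tricarboxylic acid cycle and respiratory chain fell in 21 of 24 cases (median −0.80, adjusted p = 4.73e-08, and adjusted p = 0.32 with an estimated correlation, 1 higher and 21 lower adjusted over the list alone), led by KGD2 (2.37-fold, adjusted p = 2.06e-13). Glycolysis counterparts had 5 lower and 1 higher of 7 (median −0.79, adjusted p = 0.0179, and adjusted p = 0.32 with an estimated correlation), and stress and reserve carbohydrate counterparts 6 lower of 9 (median −0.70, adjusted p = 0.0107, and adjusted p = 0.32 with an estimated correlation). Genes with at least 20 Gly-X-Y triplets, a collagen-like sequence, had 21 higher and 44 lower of 116 measured, with a median of −0.10, a mean of −0.46 and a camera adjusted p of 4.73e-08, and adjusted p = 0.32 with an estimated correlation.

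Some lists did not pass. Ribosome quality control counterparts had 3 higher and 7 lower of 14 (median −0.22, adjusted p = 0.102). The counterpart of VMS1, a release factor for stalled chains, rose (log2 0.51, SE 0.09, adjusted p = 2.32e-05), and that of ASC1, a sensor of collided ribosomes, fell from 3790 ± 253 to 1960 ± 130 CPM. Peroxisomal beta-oxidation counterparts had 3 higher and 2 lower of 6 (median 0.69, adjusted p = 0.194), with PXA1 2.55-fold higher and FAA2 1.69-fold lower. Gluconeogenesis counterparts had 4 lower of 6 (median −0.30, adjusted p = 0.0697). The 4 mitochondrial ribosome, 3 ribosome-associated chaperone and 3 amino acid biosynthesis counterparts were too few to test as lists, and 4, 3 and 2 of them were lower. Adjusted over the list alone, lists without a separate count gave the same counts, except that stress and amino acid counterparts had 1 higher each and collagen-like genes 43 lower.

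In all, 8309 of 13701 tested worm genes differed between day 12 and day 1 by edgeR, 4422 higher and 3887 lower, and 2523 and 944 of these changed at least 2-fold. Scaling by DESeq2's size factors gave 4104 higher and 4250 lower. Among genes known only by identifier, Y46H3A.5a rose 48.8-fold (from 1.11 ± 0.184 to 54.5 ± 7.22 CPM) and F56D6.10 rose 44.3-fold. The largest falls among genes with at least 50 CPM were those of W05B2.5 (13.3-fold), which shares 72.1% of its sequence windows with other genes and is uncertain, and F35B12.7.1 (75.9 ± 10.2 to 6.22 ± 3.42 CPM, log2 −3.62). The autophagy call was lost without day 12 replicate 1 (adjusted p = 0.0818). All 11 list calls were lost with an estimated correlation (adjusted p = 0.32 for each list with an estimated correlation).

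**Figure D2:**
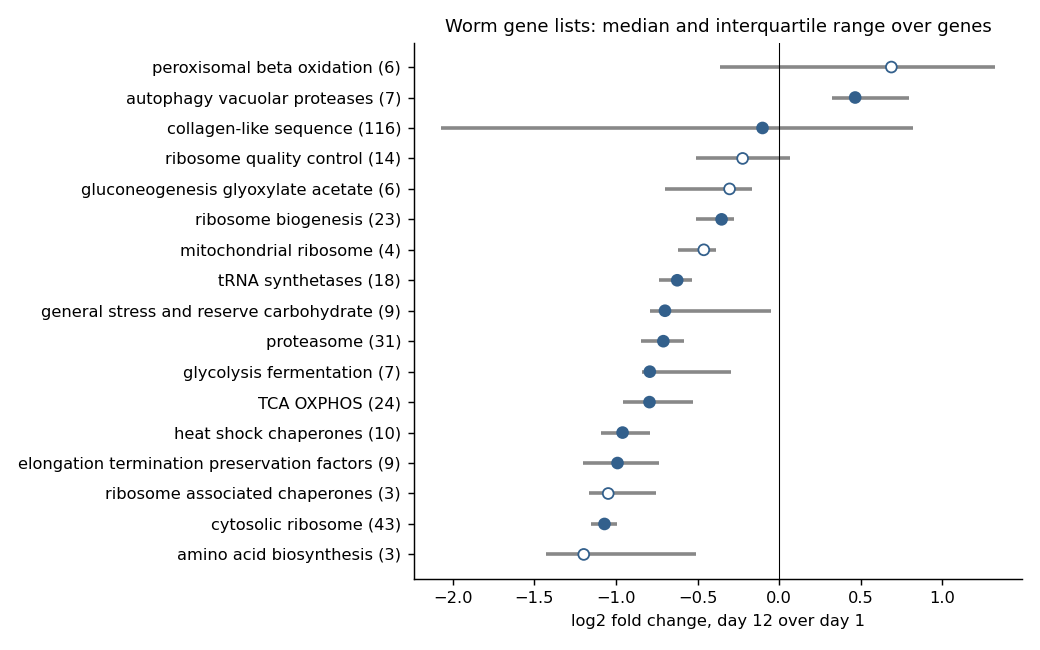
Log2 fold change of footprint counts from day 1 to day 12 in worms for counterparts of the yeast lists and for collagen-like genes, as the median (point) and interquartile range (line) over genes, with the number measured in parentheses. Filled points passed the preset-correlation test at adjusted p under 0.05, and cytosolic ribosome counterparts lay near −1.07 while autophagy counterparts lay near 0.47.

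In wild-type yeast at day 4, genes for growth on acetate, ethanol and fatty acids carried far more footprints than at day 0. All 15 genes of gluconeogenesis, the glyoxylate cycle and acetate use rose (median log2 5.57, camera adjusted p = 2.62e-13, and adjusted p = 0.26 with an estimated correlation). ACS1, encoding acetyl-CoA synthetase (chromosome I, 42881 to 45022), went from 13.8 ± 2.58 to 1260 ± 306 CPM (SD, n = 2), a 91.1-fold rise (log2 6.51, SE 0.31, adjusted p = 2.55e-07). Of 11 peroxisomal beta-oxidation genes 10 rose (median 3.79, adjusted p = 3.96e-10, and adjusted p = 0.082 with an estimated correlation), including the thiolase gene POT1 (0.819 ± 0.174 to 79.1 ± 8.07 CPM, 95.4-fold, adjusted p = 1.3e-07). Genes of the tricarboxylic acid cycle and respiratory chain rose in 43 of 45 cases (median 1.79, adjusted p = 3.52e-10, and adjusted p = 0.263 with an estimated correlation), such as the succinate dehydrogenase gene SDH2 (6.66-fold, adjusted p = 2.42e-06).

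Stress and autophagy genes rose with them. Of 25 general stress and reserve carbohydrate genes 23 rose (median 2.51, adjusted p = 6.4e-07, and adjusted p = 0.263 with an estimated correlation), among them HSP30, a plasma membrane stress protein gene, with 115 ± 15.8 CPM at day 0 and 11400 ± 2150 at day 4 (98.7-fold, adjusted p = 1.13e-06). Of 24 heat shock and chaperone genes 14 rose and 4 fell (median 0.83, adjusted p = 0.00181, and adjusted p = 0.263 with an estimated correlation). The small heat shock protein gene HSP26 (chromosome II, 382030 to 382674) rose from 278 ± 52.4 to 30600 ± 886 CPM (110-fold, adjusted p = 6.48e-07). HSP42, encoding a chaperone that sequesters misfolded proteins, was 10.9-fold higher (adjusted p = 4.73e-07), while SSA2, an abundant Hsp70 gene sharing 65% of its sequence windows and therefore uncertain, was lower (log2 −2.23). Autophagy and vacuolar protease genes rose in 14 of 16 cases (15 adjusted over the list alone; median 1.71, adjusted p = 1.19e-05, and adjusted p = 0.263 with an estimated correlation), with ATG1, the kinase that starts autophagy, higher (log2 3.65, SE 0.23) and the vacuolar protease gene PRB1 going from 515 ± 86.4 to 8370 ± 770 CPM.

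Footprints on genes of the translation machinery fell. Of 71 cytosolic ribosomal protein genes 70 were lower (median −2.198, adjusted p = 2.42e-23, and adjusted p = 0.263 with an estimated correlation), such as RPL11A (881 ± 127 to 144 ± 6.88 CPM, 6.12-fold), which shares 67.5% of its windows with its paralog and is uncertain. All 28 ribosome biogenesis genes were lower (median −1.47, adjusted p = 4.95e-11, and adjusted p = 0.263 with an estimated correlation), including NIP7 (4.34-fold, log2 −2.12, SE 0.14, adjusted p = 1.1e-06). So were all 18 tRNA synthetase genes (median −1.78, adjusted p = 1.51e-07, and adjusted p = 0.263 with an estimated correlation) and all 6 ribosome-associated chaperone genes (median −2.04, adjusted p = 0.000205, and adjusted p = 0.263 with an estimated correlation). Of the latter, EGD1, a subunit of the nascent polypeptide-associated complex, was 3.08-fold lower (log2 −1.62, SE 0.17, adjusted p = 1.53e-05). Elongation and termination factor genes were lower in 15 of 16 cases (16 adjusted over the list alone; median −1.62, adjusted p = 4.05e-06, and adjusted p = 0.263 with an estimated correlation), with TEF4 going from 2370 ± 162 to 233 ± 39.4 CPM. Proteasome genes were lower in 21 of 31 cases, by less (median −0.50, adjusted p = 0.0123, and adjusted p = 0.473 with an estimated correlation). Glycolysis genes had 14 lower and 3 higher of 18 (15 and 3 adjusted over the list alone; median −1.15, adjusted p = 0.00947, and adjusted p = 0.473 with an estimated correlation), with PFK1 2.8-fold lower and TDH1 14.9-fold higher, the latter sharing 28.8% of its windows.

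Another 4 lists did not shift as a whole, although members did. Ribosome quality control genes had 6 higher and 11 lower of 23 (median −0.05, adjusted p = 0.251). ASC1 was 4.73-fold and GCN20 2.59-fold lower, while CUE3, a ubiquitin-binding factor for stalled ribosomes, was 1.96-fold higher. Mitochondrial ribosome genes had 2 higher and 14 lower of 31 (12 lower adjusted over the list alone; median −0.30, adjusted p = 0.085). Amino acid biosynthesis genes had 15 higher and 7 lower of 31 (median 0.69, adjusted p = 0.475), with ARG1 4.84-fold higher and MET6 6.3-fold lower. Hexose transporters had 2 higher and 3 lower of 7, where the median (−0.91) and the test pointed down, the mean (0.32) up, and adjusted p was 0.792. HXT5, a transporter of slow-growing cells, rose 81.1-fold, and the low-affinity transporter gene HXT1 fell 15.9-fold (383 ± 58.8 to 24 ± 1.07 CPM), where HXT1 shares 10.6% of its windows and is uncertain. Outside the lists, the thiamine synthesis gene THI4 rose 128-fold and CHA1, encoding a serine deaminase (chromosome III, 15798 to 16880), fell 21.5-fold (adjusted p = 1.97e-05). SCH9 itself had a log2 change of 0.33 (SE 0.27, adjusted p = 0.295).

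In total 3918 of 5514 yeast genes differed by edgeR, 2049 higher and 1869 lower. At day 2 the count was 3897, with 1997 higher and 1900 lower. All 15 gluconeogenesis genes (median 5.57, adjusted p = 2.29e-13, and adjusted p = 0.223 with an estimated correlation), 44 of 45 respiratory genes (median 2.02, adjusted p = 2.29e-13, and adjusted p = 0.223 with an estimated correlation), 10 of 11 peroxisomal genes (adjusted p = 7.86e-10, and adjusted p = 0.0835 with an estimated correlation), 23 of 25 stress genes (adjusted p = 1.02e-07, and adjusted p = 0.223 with an estimated correlation) and 14 of 16 autophagy genes (adjusted p = 1.32e-05, and adjusted p = 0.223 with an estimated correlation) were already higher. All 71 cytosolic ribosomal protein genes (median −2.24, adjusted p = 1.28e-25, and adjusted p = 0.223 with an estimated correlation), 28 biogenesis genes (adjusted p = 1.55e-10, and adjusted p = 0.223 with an estimated correlation), 18 tRNA synthetase genes (adjusted p = 2.91e-08, and adjusted p = 0.223 with an estimated correlation), 16 elongation factor genes (adjusted p = 6.37e-06, and adjusted p = 0.223 with an estimated correlation) and 6 ribosome-associated chaperone genes (adjusted p = 0.00028, and adjusted p = 0.223 with an estimated correlation) were lower. HSP26 was 116-fold and ACS1 78.3-fold higher at day 2, and RLI1, the ribosome recycling factor, was 3.79-fold lower. Heat shock genes had 14 higher and 6 lower (adjusted p = 0.00771, and adjusted p = 0.223 with an estimated correlation), glycolysis genes 3 and 13 (14 lower adjusted over the list alone; adjusted p = 0.0193, and adjusted p = 0.491 with an estimated correlation), proteasome genes 18 lower (adjusted p = 0.0172, and adjusted p = 0.491 with an estimated correlation) and amino acid biosynthesis genes 5 higher and 15 lower (adjusted p = 0.0225, and adjusted p = 0.544 with an estimated correlation). Where no separate count is given, counts adjusted over the list alone were the same. With an estimated correlation no list was called at either day (lowest adjusted p = 0.0835 at day 2 and 0.082 at day 4, both for the peroxisomal genes with an estimated correlation).

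**Figure D3:**
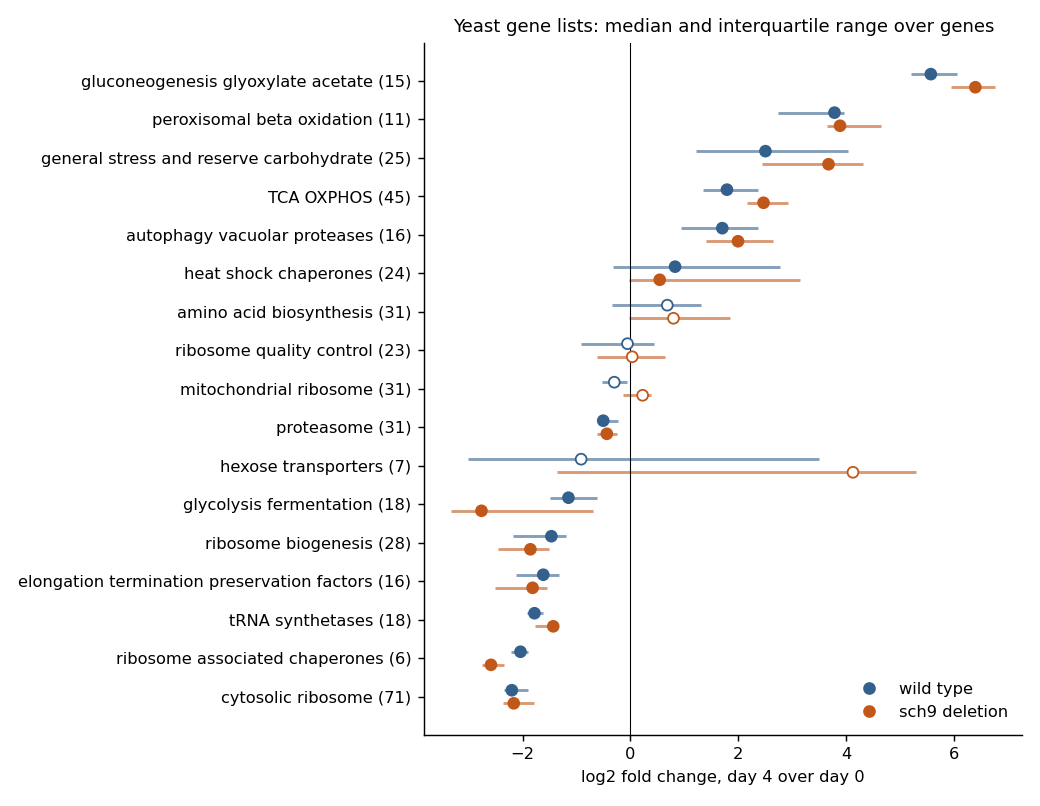
Log2 fold change of footprint counts from day 0 to day 4 in wild-type yeast and the sch9 deletion strain for each gene list, as the median (point) and interquartile range (line) over genes, with the number measured in parentheses. Filled points passed the preset-correlation test at adjusted p under 0.05, and gluconeogenesis genes lay at 5.57 and 6.40 while cytosolic ribosome genes lay at −2.198 and −2.162.

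The deletion strain underwent changes of the same kind. From day 0 to day 4, all 15 gluconeogenesis genes rose (median 6.40, adjusted p = 5.09e-12, and adjusted p = 0.255 with an estimated correlation), with ICL1, encoding isocitrate lyase of the glyoxylate cycle, going from 80.2 ± 10.9 to 10600 ± 2160 CPM (132-fold, adjusted p = 1.2e-06). All 45 respiratory genes rose (median 2.47, adjusted p = 2.07e-13, and adjusted p = 0.255 with an estimated correlation), such as SDH1 (69.5 ± 0.196 to 735 ± 45.5 CPM, 10.6-fold, adjusted p = 1.31e-07). All 25 stress genes (median 3.68, adjusted p = 3.62e-08, and adjusted p = 0.255 with an estimated correlation), 11 peroxisomal genes (median 3.89, adjusted p = 3.67e-09, and adjusted p = 0.121 with an estimated correlation) and 15 of 16 autophagy genes (median 2.00, adjusted p = 1.16e-05, and adjusted p = 0.255 with an estimated correlation) rose, including the ubiquitin gene UBI4 (17-fold) and ATG1 (15.7-fold). CRC1, the mitochondrial carnitine carrier, rose 143-fold (adjusted p = 7.42e-08). Heat shock genes had 12 higher and 4 lower of 24 (median 0.55, adjusted p = 0.0218, and adjusted p = 0.255 with an estimated correlation), with HSP42 higher (log2 4.04, SE 0.19, adjusted p = 1.18e-07).

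Glycolysis genes fell in 13 of 18 cases with 2 higher (median −2.76, adjusted p = 1.16e-05, and adjusted p = 0.255 with an estimated correlation). Triose phosphate isomerase, TPI1, went from 8400 ± 523 to 724 ± 136 CPM (11.6-fold, adjusted p = 5.92e-07) and phosphoglycerate mutase, GPM1, from 11100 ± 341 to 866 ± 77.8. The minor pyruvate kinase gene PYK2 was 2.81-fold higher. Cytosolic ribosomal protein genes were lower in 70 of 71 cases (median −2.16, adjusted p = 9.42e-18, and adjusted p = 0.255 with an estimated correlation), and all 28 biogenesis genes were lower (median −1.85, adjusted p = 5.09e-12, and adjusted p = 0.255 with an estimated correlation), for example CBF5, the pseudouridine synthase of ribosomal RNA (630 ± 21 to 70 ± 8.88 CPM). All 18 tRNA synthetase genes (median −1.43, adjusted p = 4.08e-05, and adjusted p = 0.37 with an estimated correlation), all 6 ribosome-associated chaperone genes (median −2.59, adjusted p = 0.000127, and adjusted p = 0.255 with an estimated correlation), 15 of 16 elongation factor genes (median −1.81, adjusted p = 4.39e-06, and adjusted p = 0.255 with an estimated correlation) and 20 of 31 proteasome genes (19 adjusted over the list alone; median −0.44, adjusted p = 0.0218, and adjusted p = 0.519 with an estimated correlation) were lower. HYP2 fell from 3930 ± 61.1 to 899 ± 23.2 CPM (4.37-fold), and ZUO1, a chaperone at the ribosome's exit tunnel, fell 6.93-fold.

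Among lists that did not pass, ribosome quality control genes had 7 higher and 9 lower of 23 (median 0.04, or −0.05 with DESeq2's size factors, mean −0.15 and test downward, adjusted p = 0.482). RQC2, which adds carboxy-terminal tails to stalled chains, was 2.44-fold lower (adjusted p = 4.42e-05) and CUE3 2.24-fold higher. Mitochondrial ribosome genes had 11 higher and 4 lower of 31 (10 higher adjusted over the list alone; median 0.23, adjusted p = 0.82). Amino acid biosynthesis genes had 18 higher and 4 lower of 31 (median 0.80, adjusted p = 0.151), with LEU4 8.55-fold higher. Hexose transporters had 5 higher and 2 lower of 7 (median 4.13, adjusted p = 0.708), with HXT5 94.9-fold higher and the uncertain HXT1 67.3-fold lower. The alpha-pheromone gene MF(ALPHA)2 was 100-fold lower at day 4, beside the alpha-specific genes described above.

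By edgeR 4174 of 5514 genes differed at day 4 (2260 higher, 1914 lower) and 3848 at day 2 (2151 higher, 1697 lower). Day 2 resembled day 4 in its lists, with all 45 respiratory genes (median 2.88, adjusted p = 1.29e-21, and adjusted p = 0.207 with an estimated correlation), 15 gluconeogenesis genes (adjusted p = 4.89e-14, and adjusted p = 0.207 with an estimated correlation), 25 stress genes (median 4.66, adjusted p = 5.39e-14, and adjusted p = 0.207 with an estimated correlation), 11 peroxisomal genes (adjusted p = 1.68e-11, and adjusted p = 0.0914 with an estimated correlation) and 15 autophagy genes (adjusted p = 6.2e-06, and adjusted p = 0.207 with an estimated correlation) higher. All 71 cytosolic ribosomal protein genes (adjusted p = 5.2e-24, and adjusted p = 0.232 with an estimated correlation) and 28 biogenesis genes (adjusted p = 5.39e-14, and adjusted p = 0.207 with an estimated correlation) were lower. The stress-induced repressor gene XBP1 was 57-fold higher (log2 5.83, SE 0.22, adjusted p = 5.19e-08) and RGI2, a gene of respiratory energy metabolism, 165-fold higher. Scaling by DESeq2's size factors moved the median change of all genes at day 2 from 0.13 to 0.03, a shift shared by every gene. Of the weaker calls at day 2, heat shock (adjusted p = 0.0334, and adjusted p = 0.293 with an estimated correlation) was lost without deletion-strain day 0 replicate 1 (0.0702) or day 2 replicate 1 (0.0662), and ribosome quality control (3 higher and 13 lower, adjusted p = 0.0249, and adjusted p = 0.293 with an estimated correlation) without day 2 replicate 1 (0.0543). The proteasome call at day 4 was lost without day 0 replicate 2 (adjusted p = 0.0546). No list was called with an estimated correlation (lowest adjusted p = 0.0914 at day 2 and 0.121 at day 4 with an estimated correlation).

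At day 0 the deletion strain carried fewer footprints than wild type on stress, reserve carbohydrate and respiratory genes. Of 25 stress and reserve carbohydrate genes 18 were lower (20 adjusted over the list alone), with a median log2 difference of −2.32 (camera adjusted p = 1.04e-34, and adjusted p = 0.137 with an estimated correlation). TSL1, a subunit of trehalose synthase, had 26.5 ± 1.92 CPM against 512 ± 79.2 (19.3-fold, adjusted p = 3.91e-06), and the hexokinase gene HXK1 18 ± 3.88 against 697 ± 149 (38.7-fold, adjusted p = 9.71e-06). Respiratory genes had 18 lower of 45 (32 adjusted over the list alone; median −0.72, adjusted p = 6.27e-14) and mitochondrial ribosome genes 15 lower of 31 (26 adjusted over the list alone; median −0.50, adjusted p = 4.57e-09), each with adjusted p = 0.545 with an estimated correlation. Heat shock genes had 8 lower of 24 (1 higher and 9 lower adjusted over the list alone; median −0.13, adjusted p = 0.00307, 0.528 with an estimated correlation), including HSP42 at 2.95-fold. Autophagy genes had 5 lower of 16 (7 adjusted over the list alone; median −0.42, adjusted p = 0.00373, 0.545 with an estimated correlation). Ribosome biogenesis genes had 5 higher of 28 (8 adjusted over the list alone; median 0.27, adjusted p = 0.000505, 0.763 with an estimated correlation), led by RLP7 (log2 0.82, SE 0.12, adjusted p = 0.00218).

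Of 5514 genes, 213 were higher and 385 lower in the deletion strain at day 0 by edgeR. The growth stage of the day 0 cultures was not compared between the strains, so its part in these differences is not known. The largest rises were those of the mating-type and haploid-specific genes given above, such as MF(ALPHA)2 (176-fold, adjusted p = 1.96e-06), SAG1 (146-fold, adjusted p = 3.27e-07), the mating-type switching gene HO (102-fold) and FAR1 (65.7-fold), so each group above differed beside a difference in mating-type genes. A fit of the compared groups alone called 2277 genes, and leaving out 1 library called 159 (without wild-type replicate 1), 305 (without wild-type replicate 2), 172 or 197 (without deletion-strain replicate 1 or 2).

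At day 4 the deletion strain had lower glycolysis, stress and heat shock genes. Of 18 glycolysis genes 14 were lower (1 higher and 16 lower adjusted over the list alone; median −1.64, adjusted p = 2.64e-19, and adjusted p = 0.119 with an estimated correlation), with TPI1 at 724 ± 136 against 3110 ± 226 CPM (4.3-fold, adjusted p = 0.000584). Of 25 stress genes 21 were lower (24 adjusted over the list alone; median −1.84, adjusted p = 2.64e-19, and adjusted p = 0.119 with an estimated correlation), including HSP12 (6.88-fold, adjusted p = 0.00143). Of 24 heat shock genes 7 were lower (8 adjusted over the list alone; median −0.29, adjusted p = 1.25e-05, and adjusted p = 0.119 with an estimated correlation), with HSP26 at 5730 ± 1610 against 30600 ± 886 CPM (5.34-fold, adjusted p = 0.00164). Amino acid biosynthesis genes had 9 higher of 31 (13 adjusted over the list alone; median 0.44, adjusted p = 0.00442, 0.935 with an estimated correlation), among them the histidine gene HIS4 (2.29-fold, adjusted p = 0.0155). HYP2 was 1.66-fold lower (adjusted p = 0.0165), CYC7, a cytochrome c isoform, lower (log2 −4.04, SE 0.46, adjusted p = 0.000785), and the haploid-specific scaffold gene STE5 7.56-fold higher (adjusted p = 1e-04). By edgeR 1040 genes differed, 490 higher and 550 lower. With DESeq2's size factors 391 were higher and 618 lower. A fit of the compared groups alone called 52 genes, with which 40 of the 50 genes picked by rule lost their call under some alternative other than a left-out library, and leaving out a library called 656 (wild-type replicate 2), 200 or 672 (deletion-strain replicate 1 or 2). The amino acid call was lost without deletion-strain replicate 1 (adjusted p = 0.241).

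The change from day 0 to day 4 is called ageing here for short, although it also holds the changes already present at day 2. Whether this change differed between the strains was tested as the difference of the 2 strains' changes. Glycolysis genes fell more in the deletion strain, with 7 lower and 1 higher of 18 (14 and 1 adjusted over the list alone), a median log2 difference of −1.54 and a camera adjusted p of 1.41e-09, and adjusted p = 0.643 with an estimated correlation. TPI1 (log2 −2.05, SE 0.30, adjusted p = 0.00424) and GPM1 (−2.07, SE 0.37, adjusted p = 0.0111) were among them, and PYK2 went the other way (1.89, SE 0.19, adjusted p = 0.000458). Respiratory genes rose more, with 6 higher and 1 lower of 45 (21 and 1 adjusted over the list alone; median 0.73, adjusted p = 1.44e-08, and adjusted p = 0.643 with an estimated correlation), for example SDH1 (1.37, SE 0.21, adjusted p = 0.00579). Mitochondrial ribosome genes had 4 higher of 31 (10 adjusted over the list alone; median 0.43, adjusted p = 8e-05, and adjusted p = 0.643 with an estimated correlation), led by MRPL4 (1.28, SE 0.23, adjusted p = 0.0111).

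Stress genes had 6 higher and 2 lower of 25 (10 and 5 adjusted over the list alone; median 0.68, adjusted p = 0.0032, and adjusted p = 0.643 with an estimated correlation). Among them TSL1 went from 512 ± 79.2 to 902 ± 124 CPM in wild type and from 26.5 ± 1.92 to 364 ± 98.5 in the deletion strain (log2 difference 2.96, SE 0.31, adjusted p = 0.000595), while HSP30 rose less in the deletion strain (−2.38, SE 0.49, adjusted p = 0.0204). Biogenesis genes had 2 lower of 28 (4 adjusted over the list alone; median −0.30, adjusted p = 0.00438, and adjusted p = 0.643 with an estimated correlation) and gluconeogenesis genes none of 15 by edgeR (none adjusted over the list alone; median 0.78, adjusted p = 0.0284, and adjusted p = 0.643 with an estimated correlation). All 6 calls were lost with an estimated correlation (adjusted p = 0.643 for each with an estimated correlation), and the other 11 lists had adjusted p between 0.0502 and 0.841. Heat shock genes had 2 higher and 3 lower of 24, with HSP26 (−2.28, SE 0.44, adjusted p = 0.0157) and HSP31 (−1.98, SE 0.28, adjusted p = 0.00362) rising less in the deletion strain. The largest differences were those of mating-type genes, among them SAG1 (−8.15, SE 0.36, adjusted p = 3.06e-06) and MF(ALPHA)1 (−7.43, SE 0.54, adjusted p = 6.14e-05). In total 372 genes differed, 197 higher and 175 lower, against 160 higher and 203 lower with DESeq2's size factors. Leaving out wild-type day 0 replicate 1 or 2 gave 94 or 148 genes, deletion-strain day 0 replicate 1 or 2 gave 93 or 109, and deletion-strain day 4 replicate 1 or 2 gave 178 or 211, while 701 were called by DESeq2 and 641 without the day 2 libraries. The stress and biogenesis calls were lost without deletion-strain day 4 replicate 2 (adjusted p = 0.156 and 0.109), and the gluconeogenesis call without wild-type day 0 replicate 1 (0.147), wild-type day 4 replicate 1 (0.305) or deletion-strain day 0 replicate 2 (0.0745).

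The position of ribosomes within coding sequences was compared next, since the series concerns pausing with age. Relative occupancy is the count at a codon divided by the mean count per analysed codon of its gene, so 1 is the gene's average. Runs of at least 3 lysine or arginine residues were examined first. At the third residue of the run mean relative occupancy was above 1 in every library, with 1.26 and 1.499 in the day 1 worm libraries and 1.48 and 1.68 at day 12. It was 1.69 and 1.84 in wild-type yeast at day 0 and 1.45 and 2.95 at day 4, and 1.75 and 2.23 against 1.37 and 2.17 in the deletion strain. Over the whole run and the 2 codons after it, occupancy in worms was 1.03 ± 0.16 at day 1 and 1.11 ± 0.059 at day 12 (SD, n = 2), a change of 8% (95% confidence interval −18.3% to 42.8%, limma adjusted p = 0.705). In wild-type yeast it was 1.24 ± 0.011 at day 0, 1.497 ± 0.031 at day 2 and 1.30 ± 0.344 at day 4, a change of 3% from day 0 to day 4 (−22.9% to 37.5%, adjusted p = 0.897). In the deletion strain it was 1.31 ± 0.139 and 1.16 ± 0.238 (log2 −0.19, interval −34.3% to 17.2%, adjusted p = 0.403), and the strains' changes differed by −14.7% (−43.4% to 28.3%, adjusted p = 0.701). At day 2 wild type had a change of 20.3% from day 0 with replicates that did not overlap (−9.9% to 60.7%, limma adjusted p = 0.336). The deletion strain had 1.32 ± 0.086 at day 2, a change of 1.1% from day 0 (−24.2% to 35.1%, limma adjusted p = 0.995). None of these changes passed the test, and without wild-type day 4 replicate 2 the wild-type log2 change was −0.23. The sign also turned in worms without day 1 replicate 1 (−0.05) and in the deletion strain without day 4 replicate 1 (0.02). For the difference between strains it turned without wild-type day 4 replicate 2 (0.04).

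**Figure D4:**
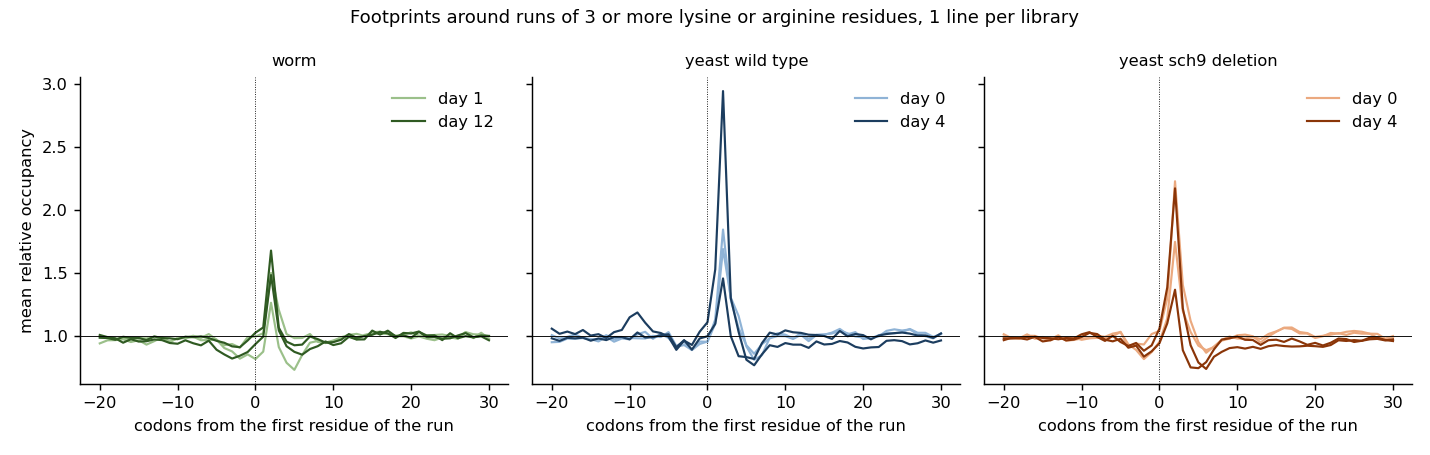
Mean relative occupancy (1 is the gene's average) by codon position from the first residue of runs of at least 3 lysine or arginine residues, with 1 line per library at the youngest and oldest ages. Occupancy peaked at the third residue in every library, and the wild-type day 4 libraries lay at 1.45 and 2.95, on either side of the day 0 libraries.

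In worms, none of 28 residues and motifs passed the limma test between day 12 and day 1, and 4 had an unadjusted p under 0.05. Tyrosine codons had the smallest, with occupancy 8.6% higher at day 12 (4.7% to 12.7%, adjusted p = 0.138). Arginine was 6.9% higher (1.3% to 12.9%), asparagine 5.4% lower (−8.9% to −1.7%) and alanine 6.2% lower (−11.3% to −0.8%), each with adjusted p = 0.246. Runs of lysine had a change of 28.7% with a wide interval (−26.9% to 126.5%, adjusted p = 0.563). Without day 1 replicate 2, 4 features were called higher, namely both definitions of basic runs, lysine runs and acidic runs.

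In wild-type yeast at day 4, occupancy rose at methionine codons by 29.3% (16.9% to 43.1%, adjusted p = 0.00466) and at asparagine codons by 15.9% (6% to 26.6%, adjusted p = 0.0448), and at glutamine codons its change was −18.7% (adjusted p = 0.00466). Methionine occupancy was 0.762 ± 0.028 at day 0, 0.903 ± 0.049 at day 2 and 0.984 ± 0.021 at day 4. From day 0 to day 2, lysine (18.2%), isoleucine (17.3%), methionine (18.5%) and asparagine (14.5%) rose and glutamine changed by −14.1% in wild type (limma adjusted p from 0.0204 to 0.0421). Asparagine (21.1%), tryptophan (−18.3%) and cysteine (−10.2%) passed in the deletion strain at day 2 (limma adjusted p from 0.0281 to 0.047). At day 4 the deletion strain had 13 changed features. Asparagine (23.2%, 12.7% to 34.6%), tyrosine (22.8%), methionine (20.9%, 9.3% to 33.7%), isoleucine (18.7%), phenylalanine (17.7%) and lysine (interval 2.9% to 22%) were higher. Tryptophan (−24.7%, −33.4% to −14.9%), runs of at least 4 acidic residues (−20.4%, −30.3% to −9.1%), glycine (−15.5%), glutamine (−13.2%), serine (−9.3%), alanine (−8.5%) and threonine (−7.3%) were lower, with adjusted p from 0.00535 to 0.047 over the 13. None of the 28 features differed between the strains in this change by limma, and 0 had an unadjusted p under 0.05. Leaving out 1 wild-type library gave 0 (day 0 replicate 1), 2, 3 or 12 (day 4 replicate 2) called features, and leaving out 1 deletion-strain library gave 7 or 5 (day 0 replicate 1 or 2), 10 or 8 (day 4 replicate 1 or 2). In wild type 11 features were called with means per gene first and 6 with a replicate block. At 2 counts per codon 6 were called, and 5 with all codons but the first and last. With the codon 1 position upstream 5 features were called in wild type, of which only methionine was among the 3. The deletion strain had 4, of which methionine, tryptophan and acidic runs were among the 13. The glutamine change of the deletion strain was then 0.02 on the log2 scale.

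**Figure D5:**
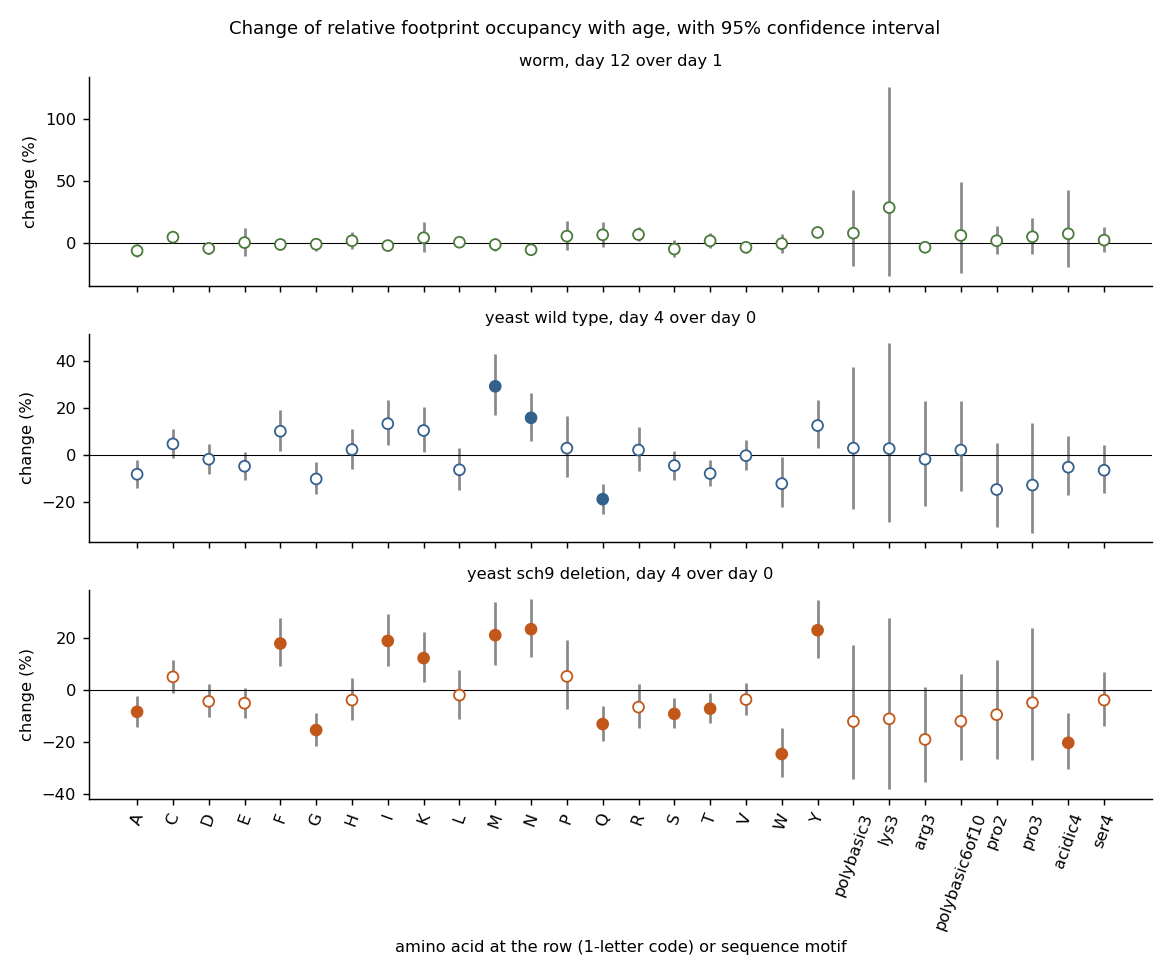
Change of mean relative footprint occupancy with age (percent, point) and its 95% confidence interval (line) for 20 amino acids in 1-letter code and 8 sequence motifs in worms, wild-type yeast and the sch9 deletion strain. Filled points passed at adjusted p under 0.05, which are 0, 3 and 13 features, and the intervals of basic runs included 0 in all panels.

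Single codon positions were tested for a change in their share of the gene's footprints. In worms none of 756084 positions passed edgeR's test, with 66371 at an unadjusted p under 0.05, whereas 1059 of 182306 positions with a mean of at least 20 counts did (918 stronger, 141 weaker). Simulated 8-fold changes under 20 counts were recovered in 45.8% of cases in worms. Among the 5 smallest p-values were those of codon 87 of the counterpart of RPL16A (341 and 346 counts at day 1, 1310 and 1227 at day 12, log2 2.73, SE 0.39, adjusted p = 0.499) and codon 125 of the counterpart of TIF35 (log2 2.73, adjusted p = 0.499). In wild-type yeast 1 of 583924 positions passed, codon 142 of MHT1, which encodes a homocysteine methyltransferase. It is a CCC proline codon and held 112 and 130 counts at day 4 (31.3% and 23% of the gene) against 25 and 30 at day 0 (2.56% and 3.29%), a log2 change of 3.21 (SE 0.39, adjusted p = 0.00429). With a mean of at least 20 counts 630 of 165796 positions passed (310 stronger, 320 weaker), while leaving out either day 0 library called none, and leaving out day 4 replicate 1 or 2 called 28 or 3.

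In the deletion strain 1491 positions passed, 316 stronger and 1175 weaker at day 4. A replicate block gave 859, and the filter at 20 counts gave 6678 (2221 stronger, 4457 weaker). Codon 245 of DCS1, an mRNA cap metabolism gene, held 41 and 73 counts at day 4 and none at day 0 (at least 5.75-fold higher against a floor of 3 counts over the group, adjusted p = 0.0422). Codon 571 of the sodium antiporter gene NHA1 was at least 6.54-fold higher on the same floor (28 and 46 counts against none, adjusted p = 0.0358), and codon 117 of PEX11, a peroxisome division gene, at least 4.36-fold (adjusted p = 0.048). Codon 45 of the phospholipid synthesis gene CDS1 went from 54 and 45 counts to none (at least 10.6-fold lower, adjusted p = 0.0162), and codon 66 of the phosphate transporter gene PHO91 was at least 13.6-fold lower (adjusted p = 0.0233). Weakened positions more often followed a stretch with at least 5 basic residues among the last 10 (2.64% against 0.71% of tested positions, two-sided Fisher's exact test p = 1.08e-09). That test treats positions as independent, but the 1175 weakened positions lay in 779 genes and all came from the same libraries. Its p-values, here and in the comparisons that follow, therefore do not measure the spread between libraries or cultures. Called positions were also not matched to tested positions on their counts, and a fall is called more easily where day 0 counts are high. These shares therefore do not tell a loss at basic stretches from a difference in counts. With the filter at 20 counts the 4457 weaker positions had 1.26% against 0.63% (p = 1.82e-06, Fisher's exact test). None of the 316 strengthened positions followed such a stretch (p = 0.182, Fisher's exact test). With the filter at 20 counts the 2221 stronger positions had 0.32% against 0.63% (p = 0.058, Fisher's exact test). In wild type the 310 stronger positions of the filter at 20 counts had 0.32% against 0.63% (p = 1, Fisher's exact test), and the 320 weaker ones had 1.88% (p = 0.0167, Fisher's exact test). In worms the 918 stronger had 1.09% against 0.68% (p = 0.153) and the 141 weaker 0.71% (p = 0.62, Fisher's exact test). Without either deletion-strain day 0 library no position was called, and without either day 4 library 4 were. None of the 583924 positions differed between the strains in this change by edgeR, with 25279 at an unadjusted p under 0.05 and 0 with the filter at 20 counts. Simulated 8-fold differences of this kind were recovered in 14.8% of cases at 20 counts or more and in 5.4% below, so most would be missed.

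The distribution of footprints along genes lay nearer the 3′ end in older yeast. The median polarity score, which runs from −1 (all footprints at the 5′ end) to 1 (all at the 3′ end), was −0.086 ± 0.0001 in wild type at day 0, −0.0083 ± 0.0129 at day 2 and 0.0247 ± 0.0735 at day 4 (SD, n = 2). In the deletion strain it was −0.0885 ± 0.0055, −0.0398 ± 0.0185 and 0.0472 ± 0.0067. The day 4 to day 0 difference was 0.111 in wild type, against a pooled SD of 0.052, and 0.0586 without day 4 replicate 2. It was 0.136 in the deletion strain, against 0.0061. The share of footprints within the first 20 codons was 8.48% ± 0.342 and 4.99% ± 0.14 in wild type at days 0 and 4, and 8.38% ± 0.619 and 5.76% ± 0.5 in the deletion strain. In worms polarity was −0.0522 ± 0.0046 at day 1, −0.0864 at day 6 and −0.0418 ± 0.0083 at day 12. Without the first and last 20 codons it was −0.069 ± 0.0144, −0.0686 and −0.031 ± 0.0064. The worm share in the first 20 codons was 5.97% ± 0.885, 9.31% and 8.08% ± 0.394. Footprints on stop codons took 1.15% ± 0.0057 of all counts in wild-type yeast at day 0. The share there was 1.78% ± 0.0948 at day 2 and 2.00% ± 0.369 at day 4. The deletion strain had 1.30% ± 0.0615, 2.81% ± 0.0849 and 1.397% ± 0.0757, and worms had 0.956% ± 0.115 and 0.684% ± 0.029 at days 1 and 12. These values were described without a test, as chosen before the data were examined.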

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

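The tests of the strains' mating type were written before the haploid-specific and a-specific genes they use were looked at, although other mating-type genes had been seen by then, and the test of swapped labels was chosen after the result was seen. Of 3 a-specific genes first chosen for a test, MFA2 was dropped because its values had already been seen, which left AGA2 and ASG7 and the same outcome.

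From day 0 to day 4, 372 genes changed differently in the deletion strain and wild type by edgeR. Glycolysis genes fell more in the deletion strain (camera adjusted p = 1.41e-09, and adjusted p = 0.643 with an estimated correlation), led by TPI1 and GPM1. Genes of the tricarboxylic acid cycle and respiratory chain (adjusted p = 1.44e-08), mitochondrial ribosome genes (adjusted p = 8e-05), stress and reserve carbohydrate genes (adjusted p = 0.0032) and gluconeogenesis genes (adjusted p = 0.0284) were shifted upwards, and ribosome biogenesis genes downwards (adjusted p = 0.00438). None of the 6 lists was called with an estimated correlation (adjusted p = 0.643 for each). No gluconeogenesis gene of 15 and only 2 biogenesis genes of 28 were called singly. The gluconeogenesis call was lost without wild-type day 0 replicate 1, wild-type day 4 replicate 1 or deletion-strain day 0 replicate 2 (adjusted p = 0.147, 0.305 and 0.0745), and the stress and biogenesis calls without deletion-strain day 4 replicate 2 (0.156 and 0.109). The deletion strain started lower at day 0 for stress (median log2 −2.32), respiratory (−0.72) and mitochondrial ribosome genes (−0.50) and higher for biogenesis genes (0.27), against median differences in ageing of 0.68, 0.73, 0.43 and −0.30. For the last 3 of these lists the starting level is about as large as the whole difference. TSL1 had 26.5 CPM in the deletion strain and 512 in wild type at day 0, and 364 and 902 at day 4.

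The same contrast moved with mating-type genes. The strains carry the same strain label, but alpha-specific and haploid-specific genes were high only in the deletion strain at day 0. A difference in mating type or ploidy beside the loss of SCH9 would also raise haploid-specific genes not yet looked at, and the median log2 difference of 7 such genes was 3.55, which is consistent with that explanation. Loss of SCH9 alone in a MATa strain would leave a-specific genes well expressed in wild type, and AGA2 and ASG7 had a median of 0.312 CPM there, which argued against it. Haploid-specific genes (HO, FAR1 and STE5) and a-specific genes (STE2 and MFA1 among others) had been seen before in the same libraries. Neither outcome is therefore independent support. Swapped labels were argued against as well, because the lowest wild-type library had 24.8 times the SCH9 CPM of the highest deletion-strain library. It stays open whether the wild type is a diploid or otherwise lacks haploid expression. It also stays open which of the 372 differences belong to SCH9, to the background or to another difference between the cultures. The growth stage of the cultures at day 0 was not compared.

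Counts outside the coding sequences were few. The highest share of a library after the stop codon was 0.3334% (deletion strain day 2 replicate 1), and the highest before the start codon was 0.0982% (deletion strain day 0 replicate 1). In worms the highest shares were 0.0797% and 0.0462%. These positions reach only 7 codons to either side, and they were not used in any test.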

How the results depend on the processing

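The alternatives here were chosen before the data were examined and none was added later, although the worm lists they were applied to were chosen after the data had been seen, and tests chosen after a result was seen stand in the other closing parts. Of 2700 values for named genes under alternatives other than a left-out library, 2641 stayed the same, 57 were weaker and 2 stronger, and of 1948 values with a library left out 1706 stayed the same, 238 were weaker, 1 was stronger and 3 changed sign. The causes of these moves were not tested. For the difference between strains, DESeq2 called 701 genes and a fit of the compared groups 641, and leaving out a library gave 93 (deletion strain day 0 replicate 1) to 553 (wild-type day 4 replicate 1). Between strains at day 0 the compared groups alone gave 2277 genes, and a left-out library 159 to 305 (wild-type replicates 1 and 2). At day 4 they gave 52, and a left-out library 200 (deletion-strain replicate 1) to 1144 (wild-type replicate 1). The age comparisons moved less. Under alternatives other than a left-out library 6869 to 8618 genes were called in worms. These gave 3804 to 4173 and 3718 to 3932 in wild type at days 2 and 4. In the deletion strain they gave 3651 to 3864 and 4112 to 4445. With an estimated correlation 0 lists were called in worms, 0 in wild type at day 2, 0 at day 4, 0 in the deletion strain at day 2, 0 at day 4, 0 for the difference between strains in ageing, and 0 and 0 between strains at days 0 and 4. With a library left out the lists called were 10 to 11 in worms, 14 to 14 and 13 to 13 in wild type at days 2 and 4, 12 to 15 and 12 to 14 in the deletion strain, 6 to 9 for the difference in ageing, and 6 to 8 and 4 to 7 between strains at days 0 and 4. For codon positions in worms, a mean of at least 20 counts gave 1059 and Fisher's exact test 86140, and every left-out library gave 0 to 0. In wild type, at least 20 counts gave 630, an offset without the position 2, all codons but the first and last 59 and Fisher's exact test 70423, with 0 to 28 on leaving out a library. In the deletion strain, at least 20 counts gave 6678 and Fisher's exact test 143073, with 0 to 4 on leaving out a library. For the difference between strains a left-out library gave 0 to 0, and Fisher's test could not be run. That test pools replicates, and between replicates of a group it called 12710 to 48036 positions. Called occupancy features in worms were 1 with the codon upstream and 0 to 4 on leaving out a library. In wild type they were 5 with the codon upstream, 11 with means per gene first, 6 at 2 counts per codon, 5 with all codons but the first and last, and 0 to 12 on leaving out a library. In the deletion strain they were 4 with the codon upstream and 5 to 10 on leaving out a library, and for the difference between strains 0 to 1. The replicate block gave 859 positions in the deletion strain and 6 features in wild type, and 305 genes for the difference between strains. Replicate numbers need not pair across groups, and the pairing correlations lay between −0.054 and 0.145 for the groups compared and between −0.269 and 0.18 over all pairs of groups. The polarity change in worms was 0.038 without the first and last 20 codons and 0.00445 to 0.0162 on leaving out a library. It was 0.127 in the deletion strain at 2 counts per codon, with 0.131 to 0.14 on leaving out a library, against 0.0586 to 0.163 in wild type. Values that changed sign were the SCH9 change in the deletion strain at day 4 (log2 0.32 without day 0 replicate 1, 0.40 without day 4 replicate 2, and at the other end −0.78 without day 4 replicate 1), the SCH9 difference between strains (0.05 without deletion-strain day 4 replicate 2, −1.13 without replicate 1), glutamine in the deletion strain (0.02 with the codon upstream), and basic runs in worms (−0.05 without day 1 replicate 1, 0.27 without replicate 2), wild type (−0.23 without day 4 replicate 2, 0.31 without replicate 1), the deletion strain (0.02 without day 4 replicate 1, −0.40 without replicate 2) and the difference between strains (0.04 without wild-type day 4 replicate 2, −0.50 without replicate 1).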

Other observations

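The test of carry-over was written before its result was seen, and the tests of a remaining gene part, of the start-codon region and of coverage were chosen after the result was seen.

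The single day 6 worm library placed the genes known only by identifier at different points of the time course. F56D6.10 had 2.73 CPM at day 1, 150.27 at day 6 and 121 at day 12, whereas Y46H3A.5a had 1.11, 0.88 and 54.5. F35B12.7.1 had 75.9, 8.22 and 6.22. Among the largest single falls in the deletion strain from day 0 to day 4 were those of the cell-wall enzyme gene UTR2 (73.6-fold by edgeR) and the phosphatase gene PHO5 (log2 −6.16), the latter uncertain because it shares 21.5% of its sequence windows. Of 61 sense codons tested singly with limma, 14 passed in worms (6 higher, 8 lower) and 30 in wild-type yeast (12 higher, 18 lower). In the deletion strain 36 passed (15 higher, 21 lower), and 0 differed between the strains. No alternative was run for this fit. Among residues and motifs from the same libraries none passed in worms, and the yeast calls moved with the library left out and with the codon position.

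Between 40 and 200 counts per library were assigned to SCH9 in the deletion strain. A part of the coding sequence left in the genome was argued against, because at least 92.9% of its 60-codon windows held counts in every library. Reads carried over from wild-type libraries would lie along the gene as random draws from the wild-type counts. In 2 of the 6 libraries, both at day 2, the correlation over codons lay below the central 95% of such draws, and in the other 4 it did not. The counts also lay on fewer codons than the central 95% of such draws in day 0 replicate 1 (66 against at least 71), day 2 replicates 1 (103 against 157) and 2 (124 against 139) and day 4 replicate 2 (55 against 62), which was looked at after the result was seen. The draws treat each count as independent and cover counting error only, and copies of a carried-over fragment would also place counts on fewer codons. By the test as written, carry-over cannot be told apart from another source, and a small admixture of cells with the gene stays open and was not tested.

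Footprints lay nearer the 3′ end of genes in older libraries of both yeast strains, without a test. Without the first and last 20 codons the change in the deletion strain was 0.1306 against a spread of 0.0145, which argued against loss of the peak near the start codon as its only cause. In wild type it was 1.55 times the spread between replicates, but this rests on 1 library, as the day 4 replicates had −0.0608 and 0.0464 against −0.0935 and −0.0874 at day 0. Whether that loss accounts for the wild-type change therefore stays open. Noise in thinly covered genes was argued against too, since genes with at least 2 counts per codon kept 93.4% or more of the change. A change of elongation or of initiation with age might move footprints in this way, as might mRNA decay from the 5′ end, and neither was tested.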
